A study of Homo sapiens with 9 samples.

How the data were processed

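RNA was measured by poly(A)-selected RNA sequencing in 9 libraries of the human line MEG-01, 3 without treatment, 3 treated with As2S2 and 3 treated with PMA. Groups and replicate numbers were taken from the sample labels. Per the labels, libraries were made with the NEBNext Ultra II kit, and per the submitters' processing notes reads were handled with fastp 0.22.0 and DESeq2. The genome builds named in those notes are zebrafish builds, and 1 control sample carries an organism label other than human, whereas the deposited tables carry human Ensembl gene IDs. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here, so no coordinates are printed.

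The authors deposited a table for each treatment against control with estimated counts (expected counts) per gene and library, which were not normalized, and TPM values (transcript abundance scaled to the same total in each library) per the file headers. The same deposited tables give a log2 fold change and an adjusted p-value per gene from the authors' comparison, in which genes without a test carry an adjusted p-value of 1. Each table held 63241 genes, of which 33676 had 0 counts in every library. The control columns stood in both tables and differed in 0 values. Between 89.9% and 91.4% of the count values per library were whole, and the others were rounded to whole numbers before testing. These shares are over all 63241 genes with values of 0 taken as whole, so among detected genes the share of whole values is lower. Total counts per library, in units of 1e6, ran from 18.2 to 20.37. Symbols were found for 62666 of the IDs in a gene name table. Intervals of count ratios are exact Poisson intervals at 95% and cover counting error only.

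Genes were kept by the filterByExpr rule of edgeR, which left 14592, and scaled by TMM. All 9 libraries entered 1 fit with the group as the factor, and each contrast was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The square root of the common dispersion was 0.0909. Errors beside log2 fold changes are SEs of the fit, and those beside CPM are SDs over 3 libraries. The 33 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, over lists with at least 5 measured members, and adjusted over the lists. The test was repeated with a correlation estimated from the data, and with fry, which tests whether a list moves one way on balance without comparing it with other genes.

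The groups, tests, gene lists, the alternatives set in advance and the rule for named genes were set before the data were examined. The rule took, for each treatment against control, the 10 genes with the highest and the 10 with the lowest log2 fold change among genes past the threshold with a mean of at least 5 CPM over all 9 libraries and no overlap between the 3 and 3 libraries (5 each way for As2S2 against PMA). It also took up to 4 members of each list with the smallest adjusted p, and a fixed set of signalling and megakaryocyte genes. The files give no gene type, so the rule was not restricted to protein-coding genes. Genes whose symbol was shared by several tested IDs (64 IDs) were left out of the highest and lowest genes. Some genes that the rule took are not reported here.

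The 33 lists covered platelet and megakaryocyte markers, lineage transcription factors, erythroid markers, SRC, RAS, MEK and ERK components, ERK-responsive genes, protein kinase C isoforms and the proplatelet cytoskeleton. They also covered metallothioneins with the zinc exporter, NRF2 targets, heat shock, ATF4, reticulum chaperones, DNA replication, mitosis, cell cycle inhibitors with D cyclins, p53 targets and apoptosis. The others held inflammatory, interferon-stimulated, matrix, adhesion, cholesterol, glycolysis, ribosome biogenesis, respiratory chain, iron, lysosome and histone genes, and monocyte, granulocyte, stem, lymphoid and endothelial markers of other cell types.

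The alternatives set in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts (at least 10 counts in every library of a group and a mean of 1 CPM), a fit of only the groups compared, the replicate number as a block, a threshold of 0.01, a log2 fold change of at least 1, an estimated correlation, and each library left out in turn. Removal of per-library trends of log2 CPM with effective transcript length, and with length and GC content, and the omission of both control replicate 2 and As2S2 replicate 1 were chosen after seeing the data. Effective lengths came from the deposited counts and TPM (99.97% of tested genes), and GC content from GENCODE 29 transcripts (96.4%). The value that shared controls give by themselves was simulated 20 times with unchanged groups.

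The fit was tested on counts simulated for all 9 libraries from the control means over 14590 genes, with changes put into the As2S2 libraries. The shares below therefore hold for expression at control levels. Of 99 genes changed 2-fold 72.7% were recovered, and of 99 changed 1.5-fold 56.6%, with 9 unchanged genes called. The genes of the mitosis list were also changed 1.5-fold and stand outside these shares, and the 9 were 5.49% of all calls, that list included.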

Results

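RNA was sequenced from MEG-01 cells, a human megakaryoblast line derived from chronic myeloid leukaemia in blast crisis, after treatment with As2S2 (arsenic disulfide), with PMA (phorbol 12-myristate 13-acetate, an activator of protein kinase C that drives this line towards megakaryocytes) or without either. Each of the 3 groups held 3 libraries. The series asks whether As2S2 promotes megakaryocyte differentiation through SRC, MEK and ERK signalling; PMA stands beside it as a known inducer. The labels give no dose and no treatment time. Total counts per library, in units of 1e6, ran from 18.2 to 20.37, and 14592 genes had enough counts to be tested. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

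The first principal component held 62.9% of the variance of the log2 CPM (counts per 1e6 counts of a library, with its total scaled by TMM) and the next held 18.8%. Control replicate 2 and As2S2 replicate 1 stood apart from the other libraries of their groups. The counts of a pair that included either of them differed by a chi-square of at least 12.6 per gene, against 2.46 to 3.56 for the other pairs. On the third component (4.61% of the variance) control replicates 1, 2 and 3 lay at 17.0, -29.8 and 10.1. As2S2 replicates 1, 2 and 3 lay at 19.7, -7.80 and -10.8. Leaving out both libraries that stood apart therefore leaves controls above 0 and As2S2 libraries below 0. Effects of As2S2 in that setting cannot be told apart from this split. PMA replicates 1, 2 and 3 lay at 3.42, -0.591 and -1.18, all below control replicates 1 and 3. With control replicate 2 left out, alone or with As2S2 replicate 1, effects of PMA cannot be told apart from that difference either. Transcripts of the mitochondrial genome took 8.04 ± 0.15% of the counts in control, 7.62 ± 0.461% with As2S2 and 10.1 ± 0.112% with PMA (mean ± SD, n = 3 libraries each). The estimated counts of some genes were not whole, which can come from reads shared out between genes, so their values are less certain. Of the genes named here, ASNS, CD68, FCGR1A, HBG1, HBG2, HSPA1A, HSPA6, HYOU1, NDRG1, PDGFRA, SHC1, SOS1, TAL1, TUBA4A and VCL held whole counts in 0 of the 9 libraries. FTH1, HBE1, HSPA1B, MAP2K1, PRSS23, SLC2A3 and SQSTM1 did so in 1, IFI6 and MYL6 in 2, and INHBE and ITGB3 in 3. The 10 most abundant genes of each library took 11.8 ± 0.183%, 11.3 ± 0.456% and 14.8 ± 0.0890% in the same order.

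The comparison of As2S2 with control asked what the arsenic compound did to the transcriptome of these cells. Metallothioneins and genes that answer oxidants rose as groups. HMOX1 (ENSG00000100292), the haem-degrading enzyme haem oxygenase 1, went from 11.2 ± 1.31 to 364 ± 34.6 CPM (n = 3 each), a log2 fold change of 5.03 ± 0.10 (SE, adjusted p = 3.11e-15, edgeR). MT2A (ENSG00000125148), a metallothionein that binds zinc and heavy metals, went from 60.2 ± 8.16 to 1886 ± 166 CPM, or 4.97 ± 0.10 on the log2 scale (adjusted p = 3.11e-15). Interferon-stimulated genes and genes of ribosome biogenesis fell as groups, together with MYC, KIT and MYB. Among the megakaryocyte genes ITGB3 rose, ITGA2B fell, and GATA1 did not pass the test.

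Among genes with a mean of at least 5 CPM whose treated and control libraries did not overlap, the next highest fold changes were those of MT1X (4.76 ± 0.11), MT1E (4.66 ± 0.09), MT1G (4.13 ± 0.09), MT1F (3.66 ± 0.13), the non-coding RNA LINC00520 (3.17 ± 0.14), the quinone reductase NQO1 (2.76 ± 0.16), the collagen chain COL9A2 (2.59 ± 0.19) and the zinc exporter SLC30A1 (2.48 ± 0.10). Their adjusted p-values lay between 3.11e-15 for MT1E and 5.65e-08 for COL9A2. The lowest by the same rule were TFPI2 (-2.65 ± 0.38), an inhibitor of serine proteases, IGFBP5 (-2.62 ± 0.18), which binds insulin-like growth factors, the hormone FGF23 (-2.61 ± 0.16), the MYC relative MYCL (-2.47 ± 0.19), the pseudogene MTDHP3 (-2.46 ± 0.14), the arginine-synthesis enzyme ASS1 (-2.44 ± 0.12), the prostaglandin-degrading enzyme HPGD (-2.39 ± 0.11), the protease PRSS23 (-2.17 ± 0.11), the collagen galactosyltransferase COLGALT2 (-2.16 ± 0.13) and the IgG receptor FCGR1A (-2.14 ± 0.15). Each of these genes passed the test. The mean of 5 CPM was taken over all 9 libraries, and TFPI2 met it only through PMA (67.2 CPM). It stood at 0.789 CPM in control and 0.121 with As2S2, or 50 and 7 summed counts. IGFBP5 stood at 6.28 CPM in control, 1.02 with As2S2 and 64.5 with PMA. The metallothioneins resemble each other, and MTDHP3 resembles its parent gene, so reads could have been split between copies. The counts give little sign of this: MT2A, MT1E, MT1F and MTDHP3 held whole counts in 9 libraries and MT1X and MT1G in 7.

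**Figure D1:**
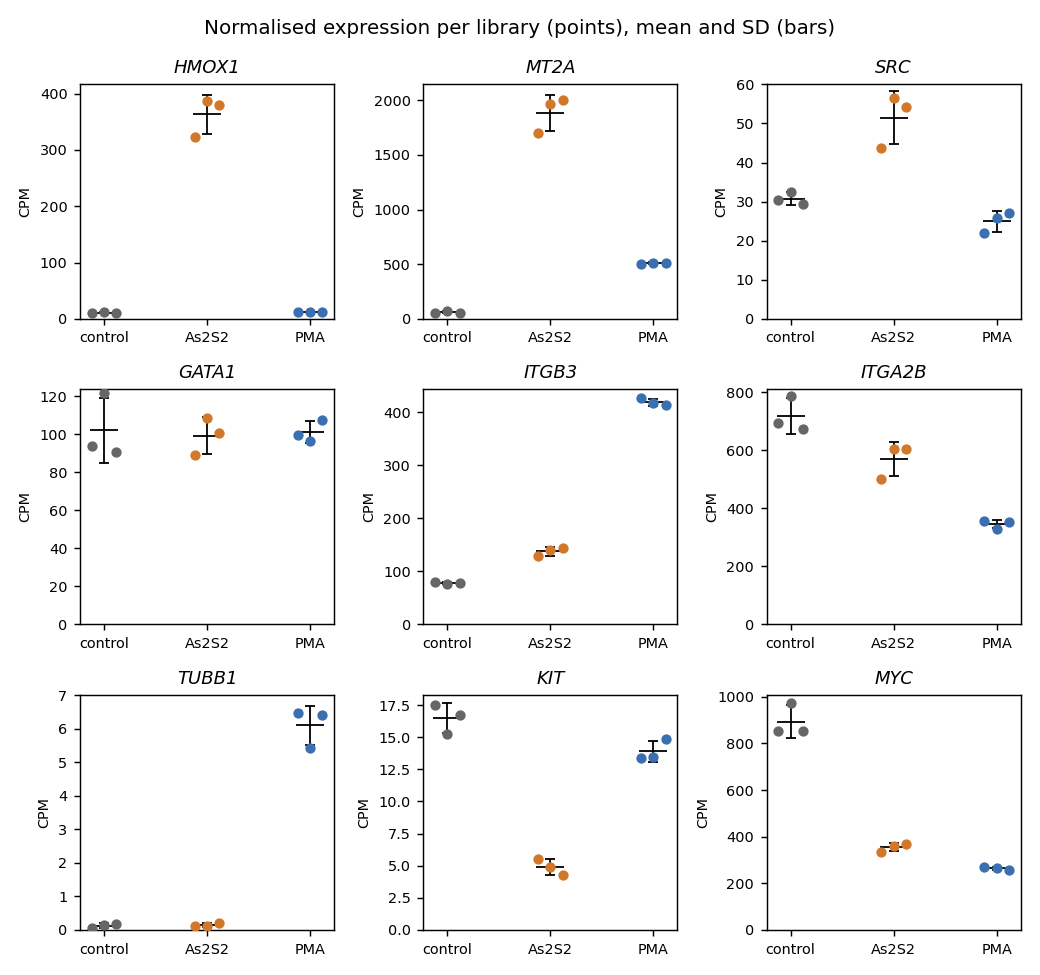
Normalised expression in CPM (vertical axes, each from 0) of 9 named genes in the 3 control, 3 As2S2 and 3 PMA libraries; points are libraries, and bars give the mean and SD. HMOX1 stood at 364 ± 34.6 CPM with As2S2 against 11.2 ± 1.31 in control and 12.3 ± 0.541 with PMA, while ITGB3 stood at 419 ± 6.60 with PMA against 78.1 ± 2.19 in control.

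All 7 measured metallothionein and zinc exporter genes rose with As2S2, with a median log2 fold change of 4.66 (all 7 also when adjusted over the list alone; adjusted p of the list 9.39e-11, camera). For MT1H, chosen after its values were seen, the control libraries held 1 count in all and the As2S2 libraries 41, a ratio of 44.7 (exact Poisson 95% interval 7.59 to 1810). Of 26 targets of NRF2, the transcription factor that answers oxidants, 19 rose, 0 fell and 7 did not pass (20 rose and 0 fell adjusted over the list alone; median 0.66, adjusted p = 6.94e-11). GCLM, a subunit of the enzyme that limits glutathione synthesis, rose by 2.08 ± 0.08, the aldo-keto reductase AKR1C3 by 2.29 ± 0.10 and the autophagy receptor SQSTM1 by 1.55 ± 0.08. Of 21 heat shock genes 15 rose and 0 fell, with the same counts adjusted over the list alone (median 0.44, adjusted p = 1.38e-05); DNAJB1 rose by 0.86 ± 0.07 and the co-chaperone BAG3 by 1.07 ± 0.09. HSPA1A rose by 1.08 ± 0.08, though it shares reads with its copy HSPA1B. Of 24 autophagy and lysosome genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.55, adjusted p = 1.07e-06), among them the galactosidase GLA (1.15 ± 0.07) and the lysosomal protease CTSA (1.22 ± 0.08). Iron and haem genes went both ways, 9 up and 8 down of 22, with the same counts adjusted over the list alone (median 0.03, adjusted p = 0.628). The ferritin chains FTH1 and FTL rose by 1.47 ± 0.08 and 1.48 ± 0.10.

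Genes for making ribosomes fell with As2S2: 22 of 29 fell and 1 rose (25 and 1 adjusted over the list alone; median -0.44, adjusted p = 6.06e-07). RRS1 changed by -0.87 ± 0.08, DKC1 by -0.65 ± 0.07 and nucleolin, NCL, by -0.66 ± 0.08. MYC, which drives this programme, went from 56458 to 20581 summed counts over the 3 libraries of each group (-1.34 ± 0.07, adjusted p = 1.21e-09). Cholesterol synthesis genes went up, 15 of 23 against 1 that fell (16 and 1 adjusted over the list alone; median 0.47, adjusted p = 2.91e-05), including INSIG1 (1.06 ± 0.08). These groups, the metallothionein, NRF2, heat shock and lysosome lists and the interferon-stimulated list also passed with an estimated correlation between genes.

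Of 32 mitosis genes 21 rose and 0 fell, with the same counts adjusted over the list alone (median 0.42, adjusted p = 4.30e-06, and adjusted p = 0.199 with an estimated correlation). CCNB1 rose by 0.89 ± 0.09, CDC20 by 0.92 ± 0.09, AURKA by 0.78 ± 0.09 and PTTG1 by 0.83 ± 0.07. DNA replication genes were split: 13 of 30 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.23, adjusted p = 0.0444, and adjusted p = 0.203 with an estimated correlation). GINS2 rose by 0.63 ± 0.10, whereas the helicase subunits MCM7 and MCM3 changed by -1.29 ± 0.07 and -0.44 ± 0.06. The list's call was lost without control replicate 1 (median 0.24, adjusted p = 0.0872), control replicate 3 (0.22, 0.0530) or As2S2 replicate 2 (0.24, 0.0506). Histone genes rose in 13 of 15 cases and fell in 0, with the same counts adjusted over the list alone (median 0.68, adjusted p = 5.55e-06, and adjusted p = 0.116 with an estimated correlation), led by H1-2 (1.70 ± 0.08) and H2BC12 (1.69 ± 0.07), which have near-identical copies. RNA was selected by poly(A), so these values cover only histone transcripts with a poly(A) tail. Respiratory chain genes rose in 12 of 30 cases and fell in 1, also adjusted over the list alone (median 0.18, adjusted p = 0.00423, and adjusted p = 0.387 with an estimated correlation). NDUFA2 stood at 0.83 ± 0.09 and COX6C at 0.54 ± 0.06.

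Genes driven by ATF4 in the integrated stress response fell in 12 of 26 cases and rose in 4, also adjusted over the list alone (median -0.18, adjusted p = 0.0387, and adjusted p = 0.457 with an estimated correlation). The asparagine synthetase gene ASNS changed by -1.15 ± 0.09, STC2 by -0.95 ± 0.08 and TRIB3 by -0.91 ± 0.11. Its call was lost without control replicate 2 (median -0.14, adjusted p = 0.145), without As2S2 replicate 1 (-0.17, 0.0997) and without both (-0.14, 0.328, chosen after seeing the data). It was also lost with the length trend removed, where the median stayed at -0.18 (adjusted p = 0.0506). It passed with the length and GC trends removed (median -0.21, adjusted p = 0.00534). Endoplasmic reticulum chaperones did not pass as a list (1 rose and 5 fell of 20, also adjusted over the list alone; median -0.07, adjusted p = 0.169), but did with no filter on low counts (0.0360). HYOU1 stood at -0.79 ± 0.07. Glycolysis and hypoxia genes did not pass either (14 rose and 4 fell of 28, 15 and 4 adjusted over the list alone; median 0.25, adjusted p = 0.0738), though the list passed without control replicate 2 (adjusted p = 0.0274), without both libraries that stood apart (0.0142) and with no filter (0.0447). NDRG1 rose by 1.14 ± 0.07 and hexokinase 2, HK2, changed by -1.13 ± 0.08.

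Platelet and megakaryocyte markers did not pass camera as a list with As2S2 (median 0.19, adjusted p = 0.218). Of 30 markers 11 rose, 7 fell and 12 did not pass (12 rose and 7 fell adjusted over the list alone). By fry, which 28 of the 33 lists passed, the list moved up on balance (adjusted p = 0.000180). The median was 0.06 without As2S2 replicate 3, 0.10 without control replicate 1, 0.12 with no filter on low counts and 0.38 without both libraries that stood apart. The list passed camera in none of these cases. ITGB3 (ENSG00000259207), the beta chain of the fibrinogen receptor, went from 78.1 ± 2.19 to 138 ± 8.08 CPM (0.82 ± 0.07, adjusted p = 1.65e-07). Its partner ITGA2B (ENSG00000005961) went from 719 ± 61.4 to 570 ± 59.5 CPM (-0.33 ± 0.08, adjusted p = 0.00422), and to -0.18 without both libraries that stood apart. The thromboxane synthase TBXAS1 rose by 1.97 ± 0.11, thrombospondin THBS1 by 1.34 ± 0.12 and the von Willebrand receptor chain GP1BA by 0.53 ± 0.13, while LTBP1 changed by -1.74 ± 0.17. TUBB1, the tubulin of platelets, held 8 counts in the control libraries and 8 in the As2S2 libraries, and did not pass the test. PF4 had 3 counts over all 9 libraries and GP5 had 1, and for TREML1 and P2RY12 there were 0, so no change in them was detectable at this depth.

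The transcription factors of megakaryocytes and red cells went both ways (7 rose and 9 fell of 23, also adjusted over the list alone; median -0.04, adjusted p = 0.218). GATA1 (ENSG00000102145) stood at 102 ± 17.2 CPM in control and 99.3 ± 9.86 with As2S2 (-0.04 ± 0.10, adjusted p = 0.803). Without both libraries that stood apart, its value was 0.18 (adjusted p = 0.0115), and with the length and GC trends removed it was -0.13 (0.0452). The first of these settings leaves out the highest control library (122 CPM) and the lowest As2S2 library (88.8 CPM), so it favours a rise. RUNX1 changed by -0.49 ± 0.07, NFE2 by -0.50 ± 0.08, MYB by -1.08 ± 0.08 and LMO2 by -1.07 ± 0.08, while TAL1 and MAFG rose by 0.60 ± 0.06 and 0.58 ± 0.07. FLI1 rose by 0.25 ± 0.08 (adjusted p = 0.0204), a call lost without control replicate 3 (adjusted p = 0.0559) or As2S2 replicate 1 (0.0519), or with only these 2 groups in the fit (0.0639). Cytoskeleton genes of proplatelets rose in 12 of 26 cases and fell in 1, also adjusted over the list alone (median 0.11, adjusted p = 0.00326, and adjusted p = 0.116 with an estimated correlation). The light chain MYL6 rose by 1.35 ± 0.07, TUBA4A by 1.89 ± 0.10 and the myosin MYH9 by 0.63 ± 0.07. The list's median was 0.20 without control replicate 2, 0.22 without control replicate 3, 0.20 without As2S2 replicate 1, 0.23 without As2S2 replicate 2 and 0.28 without both libraries that stood apart, and it passed in each case. Erythroid markers did not pass as a list (5 rose and 11 fell of 23, 6 and 12 adjusted over the list alone; median -0.29, adjusted p = 0.0855); the carbonic anhydrase CA1 changed by -0.83 ± 0.08. Stem and progenitor markers did not pass (0 rose and 5 fell of 9, 1 and 5 adjusted over the list alone; median -0.43, adjusted p = 0.113), though KIT, the stem cell factor receptor, changed by -1.76 ± 0.13 and HOXA9 by -0.61 ± 0.09. With no filter on low counts, 3 of these lists passed: the transcription factors (adjusted p = 0.0468), the erythroid markers (0.00810) and the stem and progenitor markers (0.0271).

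SRC (ENSG00000197122) rose with As2S2, from 30.8 ± 1.64 to 51.5 ± 6.88 CPM (0.74 ± 0.11, adjusted p = 5.33e-05). MAP2K1, which encodes MEK1, had a log2 fold change of 0.19 ± 0.08 (adjusted p = 0.0495), a call lost with 7 of the 9 libraries left out in turn, all but control replicate 2 and As2S2 replicate 1 (adjusted p 0.0564 to 0.146), with DESeq2 (0.0504), with RLE scaling (0.0570) and with only these 2 groups in the fit (0.136). MAP2K2 stood at 0.16 ± 0.11 (adjusted p = 0.263). MAPK3 stood at 0.26 ± 0.12 (adjusted p = 0.0839). MAP2K2 passed without control replicate 2 (0.31, adjusted p = 0.00864) and without both libraries that stood apart (0.41, 3.02e-06). MAPK3 passed without control replicate 2 (0.42, adjusted p = 0.00198), without As2S2 replicate 1 (0.34, 0.0336) and without both (0.49, 1.76e-05). It also passed with the length trend (0.27, adjusted p = 0.0488) or the length and GC trends (0.17, 0.0454) removed. With both libraries that stood apart left out, treatment cannot be told apart from the split on the third component. The calls of MAP2K2 and MAPK3 in that setting therefore do not show an effect of As2S2 alone. Leaving out only control replicate 2 or As2S2 replicate 1 removes the library of its group on the other side of 0. It thus also moves the groups apart on that component in part. As a list the SRC, RAS, MEK and ERK components did not pass camera (median 0.09, adjusted p = 0.628). Of 26 members 5 rose and 3 fell (4 and 3 adjusted over the list alone). By fry the list moved up on balance (adjusted p = 0.0352). The adaptor SHC1 rose by 0.70 ± 0.08 and the exchange factor SOS1 changed by -0.53 ± 0.09. The median of the list was 0.02 without control replicate 2, 0.03 without As2S2 replicate 1 and 0.01 without both. Phosphorylation, by which these kinases are switched on, was not measured in these libraries. Of 30 genes that respond to ERK, 10 rose and 9 fell (10 and 10 adjusted over the list alone; median -0.03, adjusted p = 0.977). The ERK phosphatase gene DUSP5 rose by 1.41 ± 0.08 and JUN by 0.89 ± 0.08, while EGR1 changed by -1.41 ± 0.10. Protein kinase C isoforms did not pass as a list (4 rose and 2 fell of 11, also adjusted over the list alone; median 0.10, adjusted p = 0.293). Their median was 0.03 without As2S2 replicate 1, 0.06 without control replicate 2, 0.15 without As2S2 replicate 2, 0.17 without control replicate 1, 0.03 without both libraries that stood apart and 0.26 with no filter on low counts. PRKCB stood at 0.78 ± 0.08.

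Interferon-stimulated genes fell with As2S2 in 24 of 27 cases and rose in 1, also adjusted over the list alone (median -1.05, adjusted p = 3.25e-09, and adjusted p = 0.0133 with an estimated correlation). MX2 changed by -3.03 ± 0.28, the ubiquitin-like ISG15 by -1.32 ± 0.12, IFI6 by -1.32 ± 0.12 and OAS1 by -1.23 ± 0.12. NF-kB and inflammatory genes did not pass as a list (12 rose and 6 fell of 25, 13 and 7 adjusted over the list alone; median 0.42, adjusted p = 0.0625). They did with no filter on low counts (adjusted p = 0.0385) and with the length and GC trends removed (0.0430). With each library left out in turn the list passed in 0 of 9 cases (median 0.29 to 0.42). NFKB2 stood at 0.94 ± 0.09, IL1B at 0.69 ± 0.07 and CCL2 at -1.21 ± 0.12. Cell cycle inhibitors and D cyclins did not pass (2 rose and 7 fell of 10, also adjusted over the list alone; median -0.31, adjusted p = 0.243): CDKN1A, which encodes p21, rose by 1.22 ± 0.10 and CCND3 by 1.42 ± 0.09, and CDKN2B changed by -1.36 ± 0.11. Targets of p53 did not pass (6 rose and 4 fell of 22, also adjusted over the list alone; median 0.04, adjusted p = 0.569), nor did apoptosis regulators (7 rose and 1 fell of 22, 8 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.135), among which BMF rose by 1.08 ± 0.14.

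Markers of other cell types gave no list that passed with As2S2. Of 10 measured monocyte and macrophage markers 2 rose and 3 fell (2 and 5 adjusted over the list alone; median -0.37, adjusted p = 0.243), and of 11 granulocyte and myeloblast markers 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.955), with a median of 0.05 but a mean of -0.03. The histidine decarboxylase HDC, in the granulocyte list, rose by 0.67 ± 0.07. Lymphoid markers had 6 measured members (3 rose and 1 fell, also adjusted over the list alone; median 1.16, adjusted p = 0.169). Their median was 0.48 without As2S2 replicate 3 and 0.65 without control replicate 2. Endothelial and stromal markers had 9 (3 rose and 2 fell, 4 and 2 adjusted over the list alone; median -0.20, adjusted p = 0.955), of which LEPR changed by -0.92 ± 0.10. That median was -0.36 without control replicate 3, -0.31 without As2S2 replicate 3, -0.13 without control replicate 1 and -0.10 without both libraries that stood apart. Extracellular matrix and protease genes had a median of -0.03 and a mean of 0.14 (9 rose and 8 fell of 21, 10 and 8 adjusted over the list alone; adjusted p = 0.487). The protease CTSL stood at 1.76 ± 0.07 and the metalloproteinase inhibitor TIMP3 at -1.04 ± 0.07. Integrins and adhesion receptors had a median of 0.02 and a mean of -0.07 (9 rose and 7 fell of 24, also adjusted over the list alone; adjusted p = 0.977); CD63 rose by 0.93 ± 0.07 and ITGA4 changed by -1.26 ± 0.12.

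In all, 5821 of the 14592 genes passed the edgeR test with As2S2, 2962 higher and 2859 lower, of which 618 and 509 changed at least 2-fold. Of the 33 lists 13 passed camera, 10 higher and 3 lower, and 7 of them with an estimated correlation. By fry, which asks only whether the genes of a list move one way on balance, 28 passed. The authors' deposited table gave 4447 genes with an adjusted p under 0.05, 2213 higher and 2234 lower with As2S2. Of the 4410 among the genes tested here, 4407 were also called, all in the same direction.

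**Figure D2:**
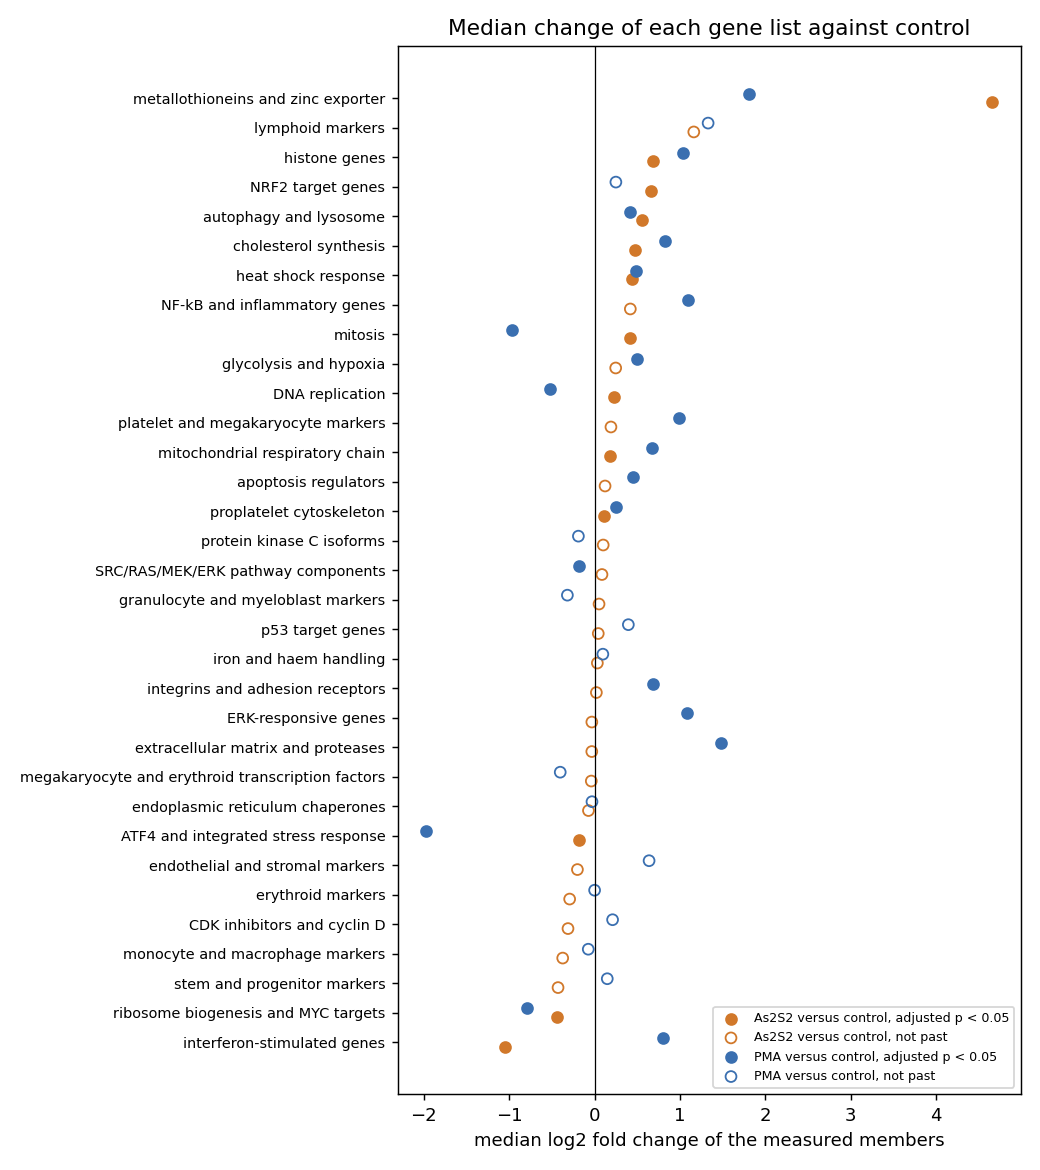
Median log2 fold change against control (horizontal axis) of the measured members of 33 gene lists (vertical axis), for As2S2 in orange and PMA in blue; filled points passed camera at an adjusted p under 0.05, and open points did not. Interferon-stimulated genes lay at -1.05 with As2S2 and 0.80 with PMA, mitosis genes at 0.42 and -0.97, and ATF4 genes at -0.18 and -1.97.

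The comparison of PMA with control shows what the known inducer did to the same cells. Platelet and megakaryocyte markers, inflammatory genes, matrix proteases and interferon-stimulated genes rose as groups. Genes of amino acid synthesis under ATF4, of ribosome biogenesis, of DNA replication and of mitosis fell, though the mitosis list did not pass with an estimated correlation (adjusted p = 0.123). GZMB (ENSG00000100453), a protease of cytotoxic granules, went from 0.273 ± 0.122 to 184 ± 5.30 CPM (9.39 ± 0.15, adjusted p = 4.54e-17, n = 3 each). INHBE (ENSG00000139269), a subunit of activin E, went from 19.5 ± 1.51 to 0.0976 ± 0.0929 CPM, with 1232 summed counts in control and 5 with PMA (-7.57 ± 0.31, adjusted p = 3.80e-12).

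By the same rule of at least 5 CPM and no overlap, the other highest genes were LY6G6C (9.18 ± 0.25), the plasminogen activator inhibitor SERPINB2 (8.82 ± 0.14), stanniocalcin 1 or STC1 (7.31 ± 0.10), the protease inhibitor A2M (7.02 ± 0.10), the regulator of G protein signalling RGS1 (6.64 ± 0.24), TFPI2 (6.40 ± 0.14) and the chemokines CCL4 (6.11 ± 0.17), CCL3L3 (6.05 ± 0.12) and CCL4L2 (6.03 ± 0.15). Summed counts in control were 7 for LY6G6C, 9 for RGS1, 17 for GZMB, 36 for CCL4 and 50 for TFPI2. These genes met the 5 CPM rule only through PMA, and the size of their fold changes rests on few control counts. The lowest after INHBE by that rule were the liver transcription factor FOXA2 (-4.49 ± 0.26), STC2 (-4.43 ± 0.10), ASS1 (-4.40 ± 0.14), the glutathione-degrading enzyme CHAC1 (-4.32 ± 0.17), the peptide ADM2 (-4.24 ± 0.16), the non-coding CHRM3-AS2 (-4.17 ± 0.15), HOXB9 (-4.17 ± 0.12), the serine-synthesis enzyme PHGDH (-4.01 ± 0.10) and NIBAN1 (-3.98 ± 0.15). Each passed the test. CCL3L3 and CCL4L2 are copies of CCL3 and CCL4, and CHRM3-AS2 lies antisense to another gene with no strand rule stated for the counts, so these values are uncertain.

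Platelet and megakaryocyte markers rose with PMA in 21 of 30 cases and fell in 6 (22 and 6 adjusted over the list alone; median 0.99, adjusted p = 0.000363, and adjusted p = 0.0401 with an estimated correlation). ITGB3 reached 419 ± 6.60 CPM (2.42 ± 0.07, adjusted p = 6.52e-14), and TUBB1 went from 8 to 318 counts (5.53 ± 0.34). The tetraspanin CD9 rose by 4.17 ± 0.14, LTBP1 by 4.33 ± 0.12 and the granule proteoglycan SRGN by 2.09 ± 0.09. ITGA2B went the other way, to 347 ± 14.5 CPM (-1.05 ± 0.08, adjusted p = 1.71e-08). GP1BA stood at 0.30 ± 0.13 (adjusted p = 0.0511) and passed without As2S2 replicate 1 (adjusted p = 0.0148). It also passed with only these 2 groups in the fit (adjusted p = 0.0246), without both libraries that stood apart (0.0169), and with the length trend (0.0258) or the length and GC trends (0.00287) removed. Proplatelet cytoskeleton genes rose in 14 of 26 cases and fell in 3, also adjusted over the list alone (median 0.25, adjusted p = 0.00995, and adjusted p = 0.123 with an estimated correlation). MYL6 stood at 1.82 ± 0.07 and vinculin, VCL, at 1.44 ± 0.08. Integrins and adhesion receptors rose in 15 of 24 cases and fell in 6 (16 and 6 adjusted over the list alone; median 0.69, adjusted p = 0.00995, and adjusted p = 0.123 with an estimated correlation). ITGB5 stood at 3.54 ± 0.13 and PECAM1 at 1.65 ± 0.09.

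Transcription factors of the lineage did not pass as a list (4 rose and 12 fell of 23, 5 and 12 adjusted over the list alone; median -0.40, adjusted p = 0.0660), but did without control replicate 1 (adjusted p = 0.0418) or control replicate 3 (0.0422) and with no filter on low counts (0.00649). Their median was -0.21 with the length trend removed (adjusted p = 0.238) and -0.18 with the length and GC trends removed (0.198). GATA1 stood at 101 ± 5.79 CPM (-0.01 ± 0.10, adjusted p = 0.928), at 0.13 without both libraries that stood apart (adjusted p = 0.0412) and at -0.13 with the length and GC trends removed (0.0282). RUNX1 changed by -0.84 ± 0.07, NFE2 by -0.50 ± 0.08, MYB by -0.96 ± 0.08 and the globin repressor BCL11A by -1.93 ± 0.16, while LMO2 rose by 1.0 ± 0.07 and FLI1 by 0.46 ± 0.08. Erythroid markers had a median just under 0 and a mean of 0.12 (8 rose and 9 fell of 23, also adjusted over the list alone; adjusted p = 0.981). Within them the embryonic globin HBE1 rose by 3.53 ± 0.08, and the foetal globin HBG2 by 2.66 ± 0.07, to 995640 summed counts from 191603; HBG2 shares reads with HBG1 (3.24 ± 0.13).

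Amino acid synthesis and stress genes under ATF4 fell in 24 of 26 cases and rose in 1, also adjusted over the list alone (median -1.97, adjusted p = 1.86e-13, and adjusted p = 0.0465 with an estimated correlation). PSAT1, which acts with PHGDH in serine synthesis, changed by -3.70 ± 0.07 and the tryptophanyl-tRNA synthetase WARS1 by -2.77 ± 0.06. Ribosome biogenesis genes fell in 25 of 29 cases and rose in 1, also adjusted over the list alone (median -0.79, adjusted p = 4.27e-07, and adjusted p = 0.0304 with an estimated correlation). DDX21 stood at -1.88 ± 0.11 and fibrillarin, FBL, at -0.96 ± 0.07. MYC, named here because of its value with As2S2, changed by -1.76 ± 0.07. DNA replication genes fell in 22 of 30 cases and rose in 3, also adjusted over the list alone (median -0.53, adjusted p = 0.000304, and adjusted p = 0.0465 with an estimated correlation). MCM3 stood at -1.08 ± 0.06 and RRM2 at -0.99 ± 0.07. Mitosis genes fell in 26 of 32 cases and rose in 3, also adjusted over the list alone (median -0.97, adjusted p = 2.46e-06, and adjusted p = 0.123 with an estimated correlation): the kinase PLK1 changed by -1.57 ± 0.08 and the proliferation marker MKI67 by -1.72 ± 0.13. CDKN1A rose by 2.84 ± 0.11 and CDKN2B by 1.43 ± 0.10, within a list that did not pass (5 rose and 2 fell of 10, also adjusted over the list alone; median 0.21, adjusted p = 0.152).

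SRC went from 30.8 ± 1.64 to 24.9 ± 2.69 CPM with PMA (-0.30 ± 0.11, adjusted p = 0.0274). The call was lost without control replicate 2 (adjusted p = 0.0528), PMA replicate 1 (0.148) or PMA replicate 2 (0.0505), and the value was -0.09 once a trend with transcript length was removed (adjusted p = 0.518) and -0.06 once length and GC trends were removed (0.527). MAP2K2 changed by -0.47 ± 0.11 (adjusted p = 0.00159), while MAP2K1 (0.13 ± 0.08, adjusted p = 0.159) and MAPK3 (0.26 ± 0.12, adjusted p = 0.0636) did not pass. MAPK3 did without control replicate 2 (0.41, adjusted p = 0.00140) and with the length and GC trends removed (0.21, 0.0116). Without both libraries that stood apart, MAP2K1 (0.14, adjusted p = 0.0423) and MAPK3 (0.41, 4.07e-05) passed. In the settings without control replicate 2 the other controls lay apart from PMA on the third component. The calls in them therefore do not show an effect of PMA alone. The SRC, RAS, MEK and ERK components fell in 12 of 26 cases and rose in 1, also adjusted over the list alone (median -0.18, adjusted p = 0.0480, and adjusted p = 0.123 with an estimated correlation). SOS1 stood at -1.77 ± 0.10. The call of the list was lost without PMA replicate 3 (median -0.20, adjusted p = 0.0513) and with the length trend (0.342, median 0.01) or the length and GC trends (0.418, median under 0.01) removed. Genes that respond to ERK rose in 22 of 30 cases and fell in 4, also adjusted over the list alone (median 1.08, adjusted p = 5.16e-05, and adjusted p = 0.144 with an estimated correlation). PHLDA1 stood at 3.89 ± 0.13, FOS at 3.22 ± 0.13, JUN at 2.64 ± 0.08 and DUSP5 at 1.88 ± 0.08. Protein kinase C isoforms did not pass (3 rose and 3 fell of 11, also adjusted over the list alone; median -0.19, adjusted p = 0.580). Their median was -0.01 with the length trend removed and 0.01 with the length and GC trends removed. PRKD3 stood at -1.02 ± 0.13 and at -0.66 with the length and GC trends removed.

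Inflammatory genes rose with PMA in 17 of 25 cases and fell in 3 (17 and 4 adjusted over the list alone; median 1.09, adjusted p = 0.000304, and adjusted p = 0.0465 with an estimated correlation). CXCL8 stood at 3.40 ± 0.12 and CCL2 at 2.79 ± 0.10. Interferon-stimulated genes rose in 22 of 27 cases and fell in 0 (23 and 1 adjusted over the list alone; median 0.80, adjusted p = 2.46e-06, and adjusted p = 0.0304 with an estimated correlation). RSAD2 stood at 2.30 ± 0.09 and IFI6 at 2.06 ± 0.11. Matrix and protease genes rose in 15 of 21 cases and fell in 3, also adjusted over the list alone (median 1.48, adjusted p = 6.31e-05, and adjusted p = 0.0465 with an estimated correlation). MMP10 stood at 4.31 ± 0.18, the protease inhibitor TIMP1 at 3.40 ± 0.10 and CTSL at 2.55 ± 0.07. Apoptosis regulators rose in 13 of 22 cases and fell in 4, also adjusted over the list alone (median 0.45, adjusted p = 0.0287, and adjusted p = 0.144 with an estimated correlation), a call lost without control replicate 2 (median 0.40, adjusted p = 0.0542). In that list the promoters of cell death BIK and BMF rose by 2.92 ± 0.23 and 2.56 ± 0.14, and the survival gene BCL2 changed by -2.29 ± 0.12. Targets of p53 did not pass (12 rose and 6 fell of 22, also adjusted over the list alone; median 0.40, adjusted p = 0.0965).

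Among the metal and oxidant genes, HMOX1 stood at 0.15 ± 0.11 (adjusted p = 0.253), and at 0.23 without both libraries that stood apart, where it passed (adjusted p = 0.0174). That setting also leaves control and PMA libraries apart on the third component. Metallothioneins and the zinc exporter rose in 5 of 7 cases and fell in 0, also adjusted over the list alone (median 1.80, adjusted p = 0.00154, and adjusted p = 0.0884 with an estimated correlation). MT2A stood at 3.09 ± 0.09. NRF2 targets did not pass (12 rose and 8 fell of 26, also adjusted over the list alone; median 0.25, adjusted p = 0.195), nor did iron and haem genes (9 rose and 8 fell of 22, also adjusted over the list alone; median 0.10, adjusted p = 0.896). Heat shock genes rose in 12 of 21 cases and fell in 3 (13 and 3 adjusted over the list alone; median 0.48, and 0.30 without control replicate 3; adjusted p = 0.00243, and adjusted p = 0.0465 with an estimated correlation). HSPA6 stood at 2.35 ± 0.13. Autophagy and lysosome genes rose in 18 of 24 cases and fell in 2, also adjusted over the list alone (median 0.42, adjusted p = 6.31e-05, and adjusted p = 0.0749 with an estimated correlation). GLA stood at 2.24 ± 0.07. Cholesterol synthesis genes rose in 19 of 23 cases and fell in 3, also adjusted over the list alone (median 0.82, adjusted p = 5.16e-05, and adjusted p = 0.0311 with an estimated correlation). SQLE stood at 1.94 ± 0.07 and MSMO1 at 2.01 ± 0.09. Endoplasmic reticulum chaperones did not pass (7 rose and 9 fell of 20, 8 and 9 adjusted over the list alone; median -0.03, adjusted p = 0.908). XBP1 stood at -1.21 ± 0.07 and MANF at 1.08 ± 0.08.

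Respiratory chain genes rose with PMA in 26 of 30 cases and fell in 0 (26 and 1 adjusted over the list alone; median 0.67, adjusted p = 4.27e-07, and adjusted p = 0.140 with an estimated correlation). With the length trend removed, 24 rose and 5 fell (median 0.48, adjusted p = 0.000143). NDUFA4 stood at 1.43 ± 0.06 and UQCRB at 1.48 ± 0.08. In the same libraries the share of mitochondrial transcripts was 10.1 ± 0.112% against 8.04 ± 0.15% in control. Short transcripts were higher and long ones lower: across genes the Spearman correlation of the log2 fold change with effective length was -0.268 under PMA and -0.00824 under As2S2 (genes are not independent replicates, so no p is given). Histone genes, which are short, rose in 12 of 15 cases and fell in 1, also adjusted over the list alone (median 1.04, adjusted p = 0.000723, and adjusted p = 0.144 with an estimated correlation). With the length trend removed their median was 0.69 (adjusted p = 0.00753). H2AC18 stood at 2.20 ± 0.10. As with As2S2, the histone values cover only transcripts with a poly(A) tail. Glycolysis and hypoxia genes rose in 19 of 28 cases and fell in 7, also adjusted over the list alone (median 0.49, adjusted p = 0.0140, and adjusted p = 0.227 with an estimated correlation). The glucose transporter SLC2A3 stood at 1.69 ± 0.06 and VEGFA at -1.46 ± 0.07.

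**Figure D3:**
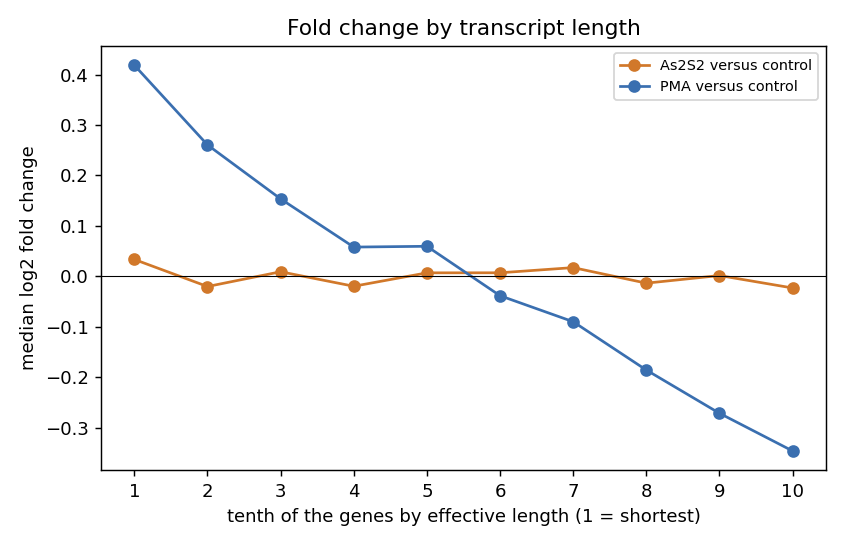
Median log2 fold change against control (vertical axis) in 10 equal bins of the tested genes ranked by effective transcript length (horizontal axis, 1 the shortest and 10 the longest), for As2S2 in orange and PMA in blue. Under PMA the median ran from 0.42 in the shortest bin to -0.35 in the longest, and under As2S2 from 0.03 to -0.02.

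Markers of other cell types did not pass as lists with PMA, except the granulocyte list when no filter on low counts was applied. Monocyte and macrophage markers went both ways (4 rose and 4 fell of 10, also adjusted over the list alone; median -0.07, adjusted p = 0.981). CD68 stood at 1.37 ± 0.08 and ITGAM at -1.88 ± 0.14. Granulocyte and myeloblast markers fell in 6 of 11 cases and rose in 1, also adjusted over the list alone (median -0.32, adjusted p = 0.0874, and adjusted p = 0.0169 with no filter). The protease CTSG stood at -4.50 ± 0.35. Stem and progenitor markers (3 rose and 2 fell of 9, also adjusted over the list alone; median 0.15, adjusted p = 0.702), lymphoid markers (4 rose and 1 fell of 6, also adjusted over the list alone; median 1.33, adjusted p = 0.328) and endothelial and stromal markers (6 rose and 2 fell of 9, also adjusted over the list alone; median 0.64, adjusted p = 0.149) did not pass. The endothelial median was 1.13 to 1.18 with any library left out but PMA replicate 1 or 2, 1.15 without both libraries that stood apart and 1.10 with no filter, and the lymphoid median was 0.74 with no filter. The stem and progenitor median was 0.04 without control replicate 1, 0.07 without control replicate 3 and 0.25 with the length trend removed. PDGFRA rose by 4.09 ± 0.18 and the collagen gene COL1A1 by 5.83 ± 0.28, from 12 to 580 counts.

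With PMA 9034 genes passed the edgeR test, 4494 higher and 4540 lower, and 1721 and 1339 of them changed at least 2-fold. With the length trend removed, 7692 of the 9034 (85.1%) kept their call and direction, against 98.7% of the calls with As2S2. Of the 33 lists 20 passed camera, 15 higher and 5 lower, with 9 left under an estimated correlation; by fry 30 passed. The authors' deposited table gave 8372 genes at an adjusted p under 0.05, 4112 higher and 4260 lower. Of the 8062 among the genes tested here, 7946 were also called, in the same direction.

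The direct comparison of As2S2 with PMA tests where the agents differ. Cells under As2S2 held more transcript of ATF4, mitosis, DNA replication, NRF2 and metallothionein genes, and less of interferon-stimulated, inflammatory, matrix and adhesion genes. Of these lists only the interferon-stimulated one also passed with an estimated correlation (adjusted p = 0.0125), and the others ranged from adjusted p = 0.0732 for DNA replication to 0.148 for inflammatory genes. By the same rule the genes highest with As2S2 relative to PMA were INHBE (5.95), HMOX1 (4.88), ADM2 (4.52), the myeloid receptor TREML2 (4.28) and CHAC1 (4.15). The lowest were LY6G6C (-9.81), GZMB (-9.35), STC1 (-9.06), TFPI2 (-9.05) and A2M (-8.65), with adjusted p-values from 6.39e-18 for STC1 to 6.12e-10 for INHBE. INHBE stood at 19.5 CPM in control, 6.34 with As2S2 and 0.0976 with PMA, so both agents lay below control. In the same order ADM2 stood at 24.4, 29.6 and 1.29 CPM and CHAC1 at 87.6, 77.6 and 4.37, so their differences came mainly from PMA. LY6G6C, TFPI2 and GZMB held 4, 7 and 16 summed counts with As2S2, so their values rest on few counts. Doses and times are not given in the sources used here, so these values set the treatments side by side as they were applied.

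Mitosis genes were higher with As2S2 than with PMA in 31 of 32 cases and lower in 0 (median 1.30, adjusted p = 1.35e-11, and adjusted p = 0.0852 with an estimated correlation), and ATF4 genes in 24 of 26 and 0 (median 1.94, adjusted p = 1.71e-13, and adjusted p = 0.0852 with an estimated correlation). DNA replication genes were higher in 23 of 30 cases and lower in 2 (24 and 2 adjusted over the list alone; median 0.75, adjusted p = 9.44e-06, and adjusted p = 0.0732 with an estimated correlation). All 7 metallothionein and zinc exporter genes were higher (median 2.67, adjusted p = 9.44e-06, and adjusted p = 0.0765 with an estimated correlation), and 18 of 26 NRF2 targets were higher and 3 lower (median 0.57, adjusted p = 0.000100, and adjusted p = 0.121 with an estimated correlation). Interferon-stimulated genes were lower with As2S2 in 24 of 27 cases and higher in 0 (median -2.01, adjusted p = 7.76e-11, and adjusted p = 0.0125 with an estimated correlation), the only list of the 15 to pass both ways. For each list in which no second pair of counts is given, the counts were the same adjusted over the list alone.

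ERK-responsive genes were lower with As2S2 than with PMA in 22 of 30 cases and higher in 4 (median -0.78, adjusted p = 6.05e-05, and adjusted p = 0.190 with an estimated correlation). PHLDA1 stood at -3.97 and FOS at -2.94. SRC itself was higher by 1.04 ± 0.11 (adjusted p = 5.52e-07), and by 0.69 with the length and GC trends removed. The SRC, RAS, MEK and ERK components were higher in 14 of 26 cases and lower in 1 (median 0.33, adjusted p = 0.0141, and adjusted p = 0.0922 with an estimated correlation). The call was lost with the length trend (median 0.18, adjusted p = 0.106) or the length and GC trends (0.11, 0.159) removed. Platelet and megakaryocyte markers just missed the threshold (10 higher and 16 lower of 30; median -0.62, adjusted p = 0.0521, and adjusted p = 0.121 with an estimated correlation). They passed without control replicate 3 (adjusted p = 0.0487), As2S2 replicate 2 (0.0345), As2S2 replicate 3 (0.0428) or PMA replicate 2 (0.0347), with no filter on low counts (0.00936), and with the length trend (0.0284) or the length and GC trends (0.0360) removed. With no filter the protein kinase C isoforms (adjusted p = 0.00936) and the cell cycle inhibitors with D cyclins (0.0261) passed as well. ITGB3 (-1.61), CD9 (-4.25) and TUBB1 (-5.41) were lower with As2S2, and ITGA2B was higher (0.72, and 0.44 with the length and GC trends removed).

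Matrix and protease genes were lower with As2S2 in 15 of 21 cases and higher in 3 (4 and 15 adjusted over the list alone, higher first; median -0.84, adjusted p = 0.000143, and adjusted p = 0.0852 with an estimated correlation), and integrins and adhesion receptors in 16 of 24 against 3 (median -0.60, adjusted p = 0.00281, and adjusted p = 0.105 with an estimated correlation). Respiratory chain genes were lower in 20 of 30 cases and higher in 0 (median -0.43, adjusted p = 4.88e-05, and adjusted p = 0.241 with an estimated correlation). With the length trend removed 13 were lower and 4 higher and the call was lost (median -0.11, adjusted p = 0.0706). With the length and GC trends removed 18 were lower and 6 higher (median -0.18, adjusted p = 0.0635). Inflammatory genes were lower in 14 of 25 cases and higher in 7 (7 higher and 15 lower adjusted over the list alone; median -0.65, adjusted p = 0.0457, and adjusted p = 0.148 with an estimated correlation). The call was lost without PMA replicate 3 (median -0.63, adjusted p = 0.0518) and without both libraries that stood apart (-0.73, 0.0776). It was also lost with the length trend (median -0.55, adjusted p = 0.0543) or the length and GC trends (-0.58, 0.0898) removed. Cholesterol synthesis genes were lower in 13 of 23 cases and higher in 4 (median -0.35, adjusted p = 0.0458, and adjusted p = 0.121 with an estimated correlation). The call was lost without control replicate 1 (median -0.34, adjusted p = 0.0510), As2S2 replicate 1 (-0.34, 0.0833), PMA replicate 3 (-0.36, 0.0518) or both libraries that stood apart (-0.34, 0.0768), and with the length trend removed (-0.32, 0.0535). With the length and GC trends removed the list passed (median -0.26, adjusted p = 0.00745). Stem and progenitor markers were lower in 5 of 9 cases and higher in 0 (median -0.47, adjusted p = 0.0437, and adjusted p = 0.122 with an estimated correlation). The call was lost without control replicate 1 (median -0.46, adjusted p = 0.0510), without As2S2 replicate 1 (-0.47, 0.0509) and without both libraries that stood apart (-0.47, 0.0561). With the length trend removed the median was further from 0, at -0.72, though the list did not pass (adjusted p = 0.0543). It passed with the length and GC trends removed (median -0.74, adjusted p = 0.0397) and with no filter on low counts (-1.03, 0.0101). Ribosome biogenesis genes were higher in 15 of 29 cases and lower in 4 (median 0.21, adjusted p = 0.0428, and adjusted p = 0.121 with an estimated correlation). Without As2S2 replicate 1 that median was 0.13 and the call was lost (adjusted p = 0.0509), and without PMA replicate 2 the median was 0.32. Without both libraries that stood apart it was 0.13, and the list passed (adjusted p = 0.0459). In the whole comparison 8966 genes passed, 4503 higher and 4463 lower with As2S2, 1392 and 1624 of them at least 2-fold. With the length trend removed, 7601 of the 8966 (84.8%) kept their call and direction. Of the lists 15 passed camera, 7 higher and 8 lower, and 30 passed fry.

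Both agents were compared with the same 3 control libraries, which by itself makes their fold changes alike. Across the 14592 genes the Pearson correlation of the log2 fold changes was 0.304. In 20 simulations of unchanged groups against these controls it was 0.477 on average (0.417 to 0.517). With unchanged groups the shared controls alone set the correlation, so the lower observed value does not measure how alike the agents were. The covariance was 0.22 against 0.0439 simulated (0.0363 to 0.0495), so the fold changes varied together beyond what the shared controls gave. Among examples chosen after their values were seen, ASS1 and MYC fell under both agents and MT2A, SQSTM1 and CTSL rose under both. In all 1514 genes rose in both where independent lists would share 912, and 1468 fell in both where 890 would be shared. Over all tested genes 61.3% had the same sign. In the simulations, where the shared controls alone set the sign, it was 66.3% (65.5% to 67.0%). LTBP1, LMO2, CDKN2B and the interferon-stimulated genes IFI6 and ISG15 were lower with As2S2 and higher with PMA, as were 499 genes in all (881 if independent), and CDC20, PLK1 and MKI67 were among the 568 that were higher with As2S2 and lower with PMA (922 if independent). The 3 controls cannot be split into parts of at least 2 libraries each, and part of the excess of shared calls may come from them.

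**Figure D4:**
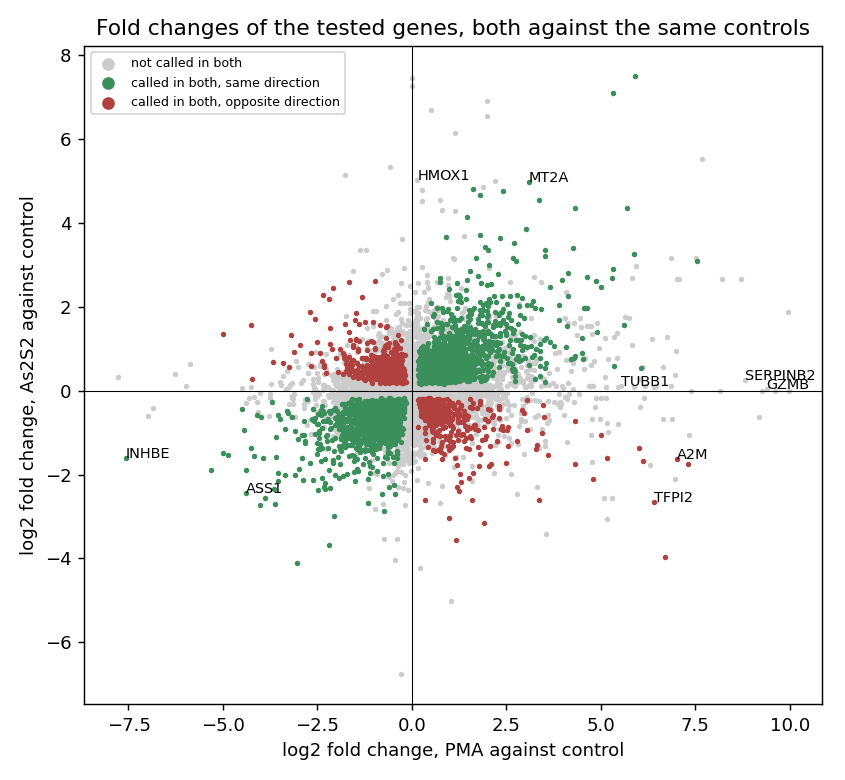
Log2 fold change against control of each tested gene under PMA (horizontal axis) and As2S2 (vertical axis); green points were called in both in the same direction, red points in both in opposite directions, and grey points are the rest. HMOX1 lies at 0.15 under PMA and 5.03 under As2S2, GZMB at 9.39 under PMA with no call under As2S2, and TFPI2 at 6.40 and -2.65.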

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

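The tests after removal of the length trend, or of the length and GC trends, and without both libraries that stood apart were chosen after the result was seen. The others were planned. Counts of genes stayed within 1.5 times under other scalings, tools, filters and a threshold of 0.01, and counts of lists under RLE scaling and no filter, the settings of this kind run for lists. Asking also for a log2 fold change of at least 1 left 1127 genes for As2S2, 3060 for PMA and 3016 for As2S2 against PMA, since that threshold removes smaller changes. With an estimated correlation 7, 9 and 1 of the 13, 20 and 15 lists passed. With each library left out in turn the counts ran from 4729 to 6320, 8282 to 9495 and 8159 to 9568. The correlation between the As2S2 and PMA fold changes, 0.304, was 0.388 with no filter and 0.284 to 0.369 with each library left out, highest without control replicate 2; the cause was not tested. GATA1 changed sign without both libraries that stood apart, to 0.18 for As2S2 (adjusted p = 0.0115, edgeR) and 0.13 for PMA (0.0412). That setting left out the highest control library (122 CPM, against 93.6 and 90.8) and the lowest As2S2 library (88.8 CPM, against 108 and 101). The change of sign thus follows from which libraries were left out and does not show a rise. Why those libraries differ was not tested. For single genes, run under RLE scaling, DESeq2, a fit of only the groups compared, the block, each library left out, both left off and the trends removed, 7221 values kept their direction and side of the threshold, 60 no longer passed, 29 newly passed and 2 reversed. Another 29 changed sign without passing in either fit. Of 51 medians of lists that did not pass, 28 moved by over 1.5 times with some library left out. Those 28 had a median size of 0.08, against 0.34 for those that did not move. Some lay far from 0, such as the lymphoid markers with As2S2 (1.16, and 0.48 without As2S2 replicate 3). With the replicate number as a block 5972, 9180 and 9044 genes and 11, 20 and 15 lists passed. The numbers were not taken as a pairing: of 9 same-numbered pairs 1 correlated over 0.1 (-0.0730 to 0.149), and 4 of the 9 libraries matched their own number best. Under the block the ATF4 and DNA replication lists with As2S2 no longer passed (both adjusted p = 0.0518). Of the genes, MAP2K1 with As2S2 no longer passed (adjusted p = 0.0568, edgeR), while MAPK3 with As2S2 (0.0426) and PMA (0.0302) and GP1BA with PMA (0.0465) newly passed. Genes with few counts are limited by depth: PF4 held 1, 0 and 2 counts in control, As2S2 and PMA.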

Other observations

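The tests of library preparation and of the interferon beta transcript, those after removal of the length or the length and GC trends, and that of the genes raised by PMA were chosen after seeing the data. For the last 2 kinds, as for the other tests, the outcomes to expect were written before their values were seen.

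Every comparison was set against the other ways to part its 6 libraries into 3 and 3. There are 10 such splits, too few for a share under 0.05. Each split other than the real split mixes the 2 groups, so the difference between them adds to the spread and lowers the calls. These splits therefore cannot decide the question. The real split was the 1 of 10 that gave as many genes in each comparison, 5821 for As2S2, 9034 for PMA and 8966 for As2S2 against PMA, and the highest of the other splits gave 0 (edgeR). At an unadjusted p under 0.05 the highest other splits gave 3041, 483 and 232 genes.

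Short transcripts were higher and long ones lower under PMA, and a candidate explanation is library preparation or RNA integrity. The contrast of short against long genes was -0.37, 0.02 and -0.27 in the control libraries, -0.26, -0.18 and -0.15 with As2S2 and 0.42, 0.44 and 0.41 with PMA. The largest range within a group was 61.4% of the shift between PMA and control, and it rests on control replicate 2. An effect of PMA itself stays open, since the same libraries carry both. After removal of the length trend the mitosis list stood at -0.94 (adjusted p = 8.49e-07, from -0.97) and the respiratory chain list at 0.48 (0.000143, from 0.67), which argues against that trend as the whole cause of either.

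Interferon-stimulated genes were lower under As2S2, with a list median of -1.05. With each library left out in turn the median nearest 0 was -0.91, and after removal of the length and GC trends it was -0.99, which argues against a single library and against those trends. A fall in the interferon beta transcript may contribute and stays open: IFNB1, chosen after its values were seen, had 23 counts with As2S2 and 35 in control, a ratio of 0.717 (exact Poisson 95% interval 0.405 to 1.25, two-sided exact p = 0.238). With PMA, where the list rose, it had 91 counts. An effect of As2S2 on the response itself was not tested.

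It was expected, from several of the strongest PMA genes such as TFPI2 and STC1, that genes raised at least 4-fold by PMA would fall under As2S2. They did not as a set: of 573 such genes 183 rose and 43 fell under As2S2, so that 19.0% of those called fell (14.8% to 19.7% with each library left out). Among the 75 with at least 5 CPM in control, 48 rose and 16 fell. Of the 240 genes that PMA lowered at least 4-fold, 26 rose and 104 fell. The shared control libraries push both comparisons towards the same sign, so these shares do not measure a shared response.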
